A study of Mus musculus with 8 samples.

How the data were processed

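Total RNA of 8 mouse prostate samples was measured on Illumina expression beadchips, 1 array per sample. Groups followed the labels: wild type at 30 weeks (2 arrays), untreated TRAMP at 30 weeks (2), TRAMP with cromolyn from 8 weeks, taken at 24 weeks (3), and TRAMP with the KitW-sh genotype at 24 weeks (1). The values used were the deposited intensity of each of 25697 probes, on a linear scale. Per the submitters' processing notes BeadStudio was used, with no version given. The sorted values of the 8 arrays differed by at most 0.0489 on the log2 scale, so the deposited values had been quantile normalized, and their lowest values lay well above 0, so background had not been subtracted. A further table with 8 columns of per-sample signals names its columns by slide position, which no label ties to a sample, and was not used here. Because of this the planned correction from detection p-values (offset 16, detection p under 0.01) was replaced by its planned fallback, limma's normexp correction of the deposited intensity with offset 50, followed by quantile normalization and log2. The filter on detection p was replaced, after the values were seen, by an intensity limit. The background mode (181.3) and SD (15.3) were estimated from the dim side of the distribution of intensities, and the limit, 216.9, was set where 0.01 of such a background would lie above it.

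Of the probes, 18003 were above that limit on at least 1 array and 14492 to 14512 on each array, which is 56.4% to 56.5%. For each gene the probe with the highest mean level was kept. A single gene name was paired with 23978 probes, none had several, and 1719 had no name here and stayed on their own. Names were updated through a gene table of assembly GRCm38.p6, in which 23962 probes found a gene, and no coordinates were used. This left 13025 features (11943 named genes and 1082 unnamed probes), called genes in the counts. Of 3400 genes with several probes, probes called in opposite directions were seen in 5 genes for cromolyn against untreated TRAMP, 1 for KitW-sh against untreated TRAMP, 27 for cromolyn against wild type, 9 for KitW-sh against wild type and 0 in the other comparisons, none of them a gene named here. The number of arrays limits the precision of all values.

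Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group and 1 residual spread pooled over all 8 arrays (4 residual and 2.62 prior degrees of freedom), so that the lone KitW-sh array was assumed to vary like the others. P-values are two-sided and were adjusted by Benjamini and Hochberg within each of 6 comparisons, and genes at an adjusted p under 0.05 were called. The 3 main comparisons were untreated TRAMP against wild type, cromolyn against untreated TRAMP and KitW-sh against untreated TRAMP. The gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over 27 lists within a comparison, and again with an estimated correlation, which also sets the degrees of freedom of the test to the 4 residual ones. With it, 2, 1 and 1 lists were called in the main comparisons in place of 15, 17 and 13. Against wild type the preset correlation gave 18 lists with cromolyn and 12 with KitW-sh, and the estimated one gave 0 of the 27 in each. Median, mean and test differed in sign in 2 lists of every comparison but KitW-sh against cromolyn, where it was 4, and none of these was called. Where no array of a group was above the limit, folds were computed against the limit on the log2 scale, which was 7.01, and a list's median is also given with such members at their bound where that moved it by more than 0.1.

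Groups, comparisons, lists and the rule for named genes were chosen before the data were examined. Named were the 8 highest rises and 8 largest falls among called genes whose groups do not overlap, leaving out clone and prediction labels, a fixed panel of 20 genes, and for each list that passed up to 4 members with the smallest p in its direction (2 for other lists). Some genes of the panel are not reported here. Gene families in the closing part were chosen after their values were seen. Cromolyn and KitW-sh effects were compared across genes with 100 simulations of unchanged groups sharing the same untreated arrays.

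The steps were tested on simulated data with 50 genes changed at each size among 13025 and noise independent between genes. In the data far more genes were called, 37.0% with cromolyn and 22.6% with KitW-sh against untreated TRAMP. The adjusted threshold is looser when many genes change, so the simulated rates need not hold for these comparisons. A log2 change of 2 was recovered in 84.0% of genes for untreated TRAMP against wild type, 86.0% for cromolyn and 72.0% for KitW-sh against untreated TRAMP, 84.0% and 64.0% for these against wild type and 76.0% for KitW-sh against cromolyn. A log2 change of 1 was recovered in 20.0%, 16.0%, 2.0%, 28.0%, 2.0% and 10.0%, and a change of 4 in 96.0%, 98.0%, 98.0%, 100.0%, 96.0% and 98.0%. Among 12825 unchanged genes 4 to 10 were called. Alternatives were no background correction, median scaling, cyclic loess, no filter, a filter on 2 arrays, an intensity trend, a fit of only the 2 groups compared, the replicate number as a block, the mean of a gene's probes, a log2 difference of at least 1, an estimated correlation and each array left out in turn. A normexp offset of 16, centring on genes above background on all arrays, a split of the 2 untreated TRAMP arrays between the cromolyn and KitW-sh comparisons, and the estimated correlations and their degrees of freedom each taken alone were chosen after seeing the data. No comparison has 3 arrays on both sides, so other splits of the arrays were not counted.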

Results

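RNA from mouse prostates was measured on 8 expression beadchip arrays, which report the brightness of a probe for each transcript. All mice were of the C57Bl/6 strain. TRAMP mice carry a transgene that drives viral T antigens in prostate epithelium and develop prostate tumours. Non-tumour prostates of wild-type mice (n = 2) and tumours of untreated TRAMP mice (n = 2) were taken at 30 weeks. Tumours of TRAMP mice given cromolyn, a drug that stabilises mast cells, from 8 weeks of age (n = 3), and a tumour of a TRAMP mouse with the KitW-sh genotype, which lacks mast cells (n = 1), were taken at 24 weeks. The design asks how tumours differ when mast cells are blocked by a drug or absent by genotype. Age goes with these groups, since the untreated tumours were 6 weeks older. The number of arrays limits the precision, and nothing in the labels says that replicates were separate animals. The limma p-values of genes therefore measure only the spread between these samples, which may be technical. The camera p-values of lists with the preset correlation rest mainly on the spread between genes. They do not measure the spread between samples, however small they are. Levels are given as log2 intensity, differences as log2 difference ± SE, and gene calls as limma adjusted p.

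The arrays fell into a 30-week and a 24-week set. Across 13025 genes and unnamed probes, which are not independent replicates, correlations were 0.967 between the wild-type arrays, 0.984 between the untreated TRAMP arrays and 0.922 to 0.934 between these groups. Cromolyn arrays correlated with each other at 0.93 to 0.966 and with the KitW-sh array at 0.938 to 0.975. Untreated TRAMP arrays reached only 0.771 to 0.796 with cromolyn arrays and 0.822 to 0.825 with the KitW-sh array. The first principal component held 71.1% of the variance and parted the 24-week tumours from the other arrays, and the second, with 10.96%, parted wild type from untreated TRAMP.

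Genes of the KitW-sh locus and of mast cells were examined first. The W-sh rearrangement lies on the chromosome near Corin, a serine protease gene whose expression it affects. Corin was not above background in the KitW-sh tumour (6.58) and was above it on all other arrays: 8.35 ± 0.02 in wild type (SD, n = 2), 9.03 ± 0.03 in untreated TRAMP (SD, n = 2) and 10.42 ± 1.86 with cromolyn (SD, n = 3). The KitW-sh tumour was at least 4.06-fold below untreated TRAMP, a difference that did not pass (adjusted p = 0.22). Corin spread widely among the cromolyn arrays. Without TRAMP_cromolyn replicate 1 the adjusted p was 0.00238, and with only the 2 groups compared it was 0.000576. Cpa3, the mast cell carboxypeptidase, was at 9.04 ± 0.49 in wild type and 8.19 ± 0.51 in untreated TRAMP (SD, n = 2 each) and was not above background in any 24-week tumour. It fell at least 2.26-fold with cromolyn (adjusted p = 0.0080) and at least 2.26-fold with KitW-sh (adjusted p = 0.0268) against untreated TRAMP. Without TRAMP_30wk replicate 1 these adjusted p values were 0.0671 and 0.113. The chymase gene Cma1 lay near background in untreated TRAMP (7.32), as did the tryptase gene Tpsb2 (7.16, above background on 1 of 2 arrays), and neither was above background in the 24-week tumours. Of 11 mast cell markers, 3 fell with cromolyn over all genes tested and 3 adjusted over the list alone (Cpa3, Mcpt4 and Gata2), and the list's shift passed at adjusted p = 0.0414 (median -0.52, or -0.30 with members at their bound, adjusted p = 0.513 with an estimated correlation). Like Cpa3, Mcpt4 and Gata2 lost their calls without TRAMP_30wk replicate 1 (adjusted p = 0.109 and 0.106), and Gata2 also without TRAMP_30wk replicate 2 (0.0842). The list's call was lost without TRAMP_30wk replicate 1 (fitted median -0.28, adjusted p = 0.162), TRAMP_cromolyn replicate 1 (0.057) or TRAMP_cromolyn replicate 2 (0.0588). With KitW-sh 1 of 11 fell over all genes and 1 adjusted over the list alone (list adjusted p = 0.404), and in untreated TRAMP against wild type 1 fell and 1 adjusted over the list alone, Hdc (list adjusted p = 0.0513; 0.00615 without wild_type replicate 1 and 0.00687 without TRAMP_30wk replicate 1). Hdc lost its own call without wild_type replicate 1 (adjusted p = 0.0604), wild_type replicate 2 (0.13) or TRAMP_30wk replicate 2 (0.144). Kitl, the stem cell factor gene, rose with cromolyn (1.75 ± 0.17, adjusted p = 0.000483) and with KitW-sh (1.66 ± 0.23, adjusted p = 0.0041). This rests on 1 of 2 probes, with intensities of 240.5 and 235.3 in untreated TRAMP, near the limit of 216.9. The other Kitl probe was not above background on any array.

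**Figure D1:**
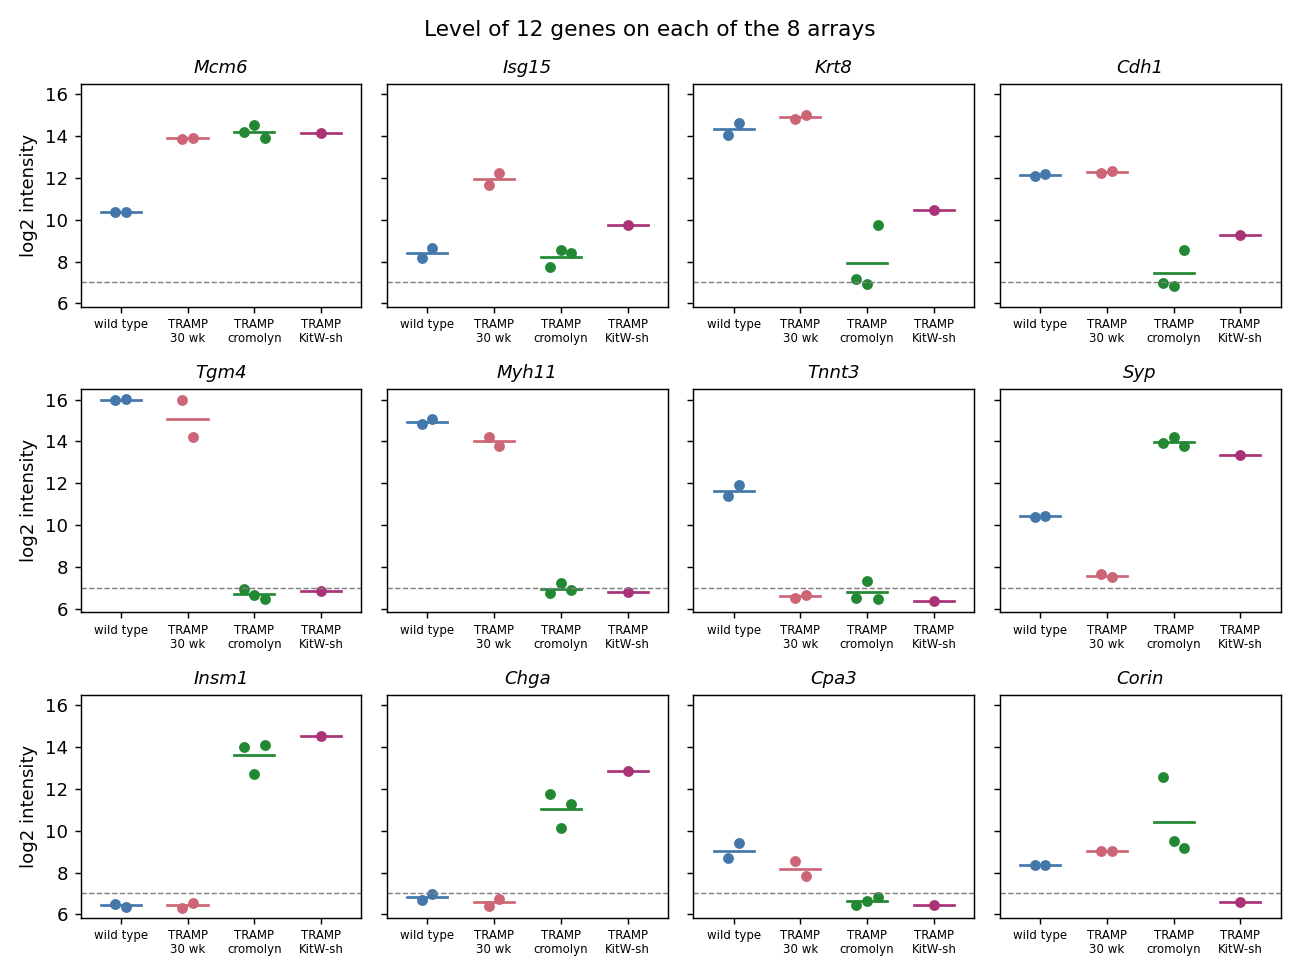
Each panel shows the log2 intensity of 1 gene on the 8 arrays by group, with a point per array, a solid line at the group mean and a dashed line at the mean lower limit of values above background. Syp reached 13.99 with cromolyn and 13.34 with KitW-sh against 7.59 in untreated TRAMP, while Krt8 and Myh11 were high in wild type and untreated TRAMP.

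The untreated TRAMP tumours were set against wild-type prostate to show what the tumour carries at 30 weeks. As lists, cell cycle and interferon response genes shifted up in the tumours, and skeletal muscle, adipocyte and neuroendocrine granule genes shifted down. The cell cycle and neuroendocrine granule shifts also passed with an estimated correlation (adjusted p = 0.046 each), and the others did not (adjusted p = 0.114 for interferon response, 0.114 for skeletal muscle and 0.298 for adipocyte genes, each with an estimated correlation). Counts were 487 genes higher and 377 lower of 13025 (adjusted p under 0.05), of which 3 and 27 differed at least 16-fold. The balance depended on the scaling: higher and lower genes numbered 454 and 448 with cyclic loess and 443 and 447 with centring on genes above background on all arrays. The largest rises were in Cdkn2a, a cell cycle inhibitor gene (at least 42.3-fold, adjusted p = 0.000835), the trefoil factor gene Tff3 (at least 32.5-fold) and Obp2a (at least 16.1-fold), none of which was above background in wild type. Atp4a rose by 3.96 ± 0.29, Isg15 by 3.53 ± 0.35, Mcm6 by 3.53 ± 0.23, Ctse by 3.52 ± 0.67 and Rad54b by 3.39 ± 0.19. The largest falls were in the beta-defensin gene Defb42 (-7.66 ± 0.46, above background on 1 of 2 tumour arrays), Wfdc3 (-6.50 ± 0.98), the muscle calcium pump gene Atp2a1 (-6.26 ± 0.90, on 1 of 2), Myh8 (-5.55 ± 0.53, on 1 of 2), Tnni2 (-5.17 ± 0.74), Adipoq (-5.07 ± 0.99, on 1 of 2), Myl3 (at least 35.4-fold) and Serpina1f (at least 30-fold). A fold given as at least a value was computed against the lower limit of values above background, because no array of 1 group was above it. Of these genes, 5 lost their calls without TRAMP_30wk replicate 1 or replicate 2: Wfdc3 (adjusted p up to 0.0976), Atp2a1 (0.0857), Tnni2 (0.0848), Adipoq (0.198) and Ctse (0.176). Wfdc3 also lost its call without wild_type replicate 1, Tnni2 without wild_type replicate 2, Atp2a1 and Adipoq without either of these, Ctse without TRAMP_cromolyn replicate 1 or 3, and Adipoq without TRAMP_cromolyn replicate 3.

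Cell cycle and E2F target genes rose in untreated TRAMP: 30 of 34 passed over all genes and 31 adjusted over the list alone. The cell cycle median was 2.34 (camera adjusted p = 1.24e-34, and adjusted p = 0.046 with an estimated correlation). Mcm2 rose by 3.10 ± 0.20 and Uhrf1, which maintains DNA methylation, by 2.59 ± 0.16. Interferon response genes rose in 15 of 27 cases, 18 adjusted over the list alone, among them Rsad2 (2.75 ± 0.25) and Oasl2 (2.87 ± 0.31). The interferon response median was 1.44 (camera adjusted p = 3.85e-14, and adjusted p = 0.114 with an estimated correlation). Antigen presentation genes went the same way in 5 of 20, 7 adjusted over the list alone, with H2-K1 at 1.83 ± 0.25, and this list's call was lost without wild_type replicate 1 (adjusted p = 0.275). The antigen presentation median was 0.41 (camera adjusted p = 0.00368, and adjusted p = 0.499 with an estimated correlation). Markers of macrophages (median 0.32, adjusted p = 0.766) and of T and NK cells (median -0.05, mean 0.06, adjusted p = 0.905) did not pass as lists. Without wild_type replicate 1 their medians were -0.75 (adjusted p = 0.000254) and -0.25 (0.0405), and without wild_type replicate 2 they were 1.11 (1.77e-06) and 0.28 (0.0193). The T cell and NK cell effector gene Prf1 fell (-2.15 ± 0.26), as the 1 member of its list to pass over all genes and adjusted over the list alone. Without TRAMP_30wk replicate 2 the adjusted p was 0.0682 for Prf1 and 0.0915 for H2-K1, and without TRAMP_30wk replicate 1 it was 0.0558 for H2-K1. Without wild_type replicate 1 the antigen presentation median was 0.15 and the immediate early median 0.23, and without wild_type replicate 2 they were 0.88 and 0.72. Immediate early and heat shock genes rose in 2 of 19, 3 adjusted over the list alone, and this call too was lost without wild_type replicate 1 (adjusted p = 0.138). The immediate early median was 0.42 (camera adjusted p = 0.00598, and adjusted p = 0.499 with an estimated correlation).

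Skeletal muscle genes fell in 15 of 19 cases, 18 adjusted over the list alone. The skeletal muscle median was -3.99 (camera adjusted p = 2.29e-21, and adjusted p = 0.114 with an estimated correlation). Tnnt3 fell at least 24.7-fold and the muscle creatine kinase gene Ckmt2 at least 18.5-fold. Adipocyte genes fell with them in 7 of 15, 12 adjusted over the list alone. The adipocyte median was -1.53, or -1.38 with members at their bound (camera adjusted p = 5.4e-08, and adjusted p = 0.298 with an estimated correlation). Neuroendocrine granule and synaptic genes fell in 7 and rose in 1 of 26, 12 and 1 adjusted over the list alone, led by the synaptic vesicle gene Syp (-2.85 ± 0.20). The neuroendocrine granule median was -1.22, or -0.85 with members at their bound (camera adjusted p = 1.47e-07, and adjusted p = 0.046 with an estimated correlation). Schwann cell and nerve genes had no member past the test over all genes and 4 of 9 lower adjusted over the list alone; the list's call was lost without wild_type replicate 2 (adjusted p = 0.186). The Schwann cell median was -1.01 (camera adjusted p = 0.0182, and adjusted p = 0.339 with an estimated correlation). Basal epithelial markers fell in 2 of 14, 5 adjusted over the list alone: Trp63, the basal cell regulator, fell by 2.39 ± 0.20 and Krt15 by 3.46 ± 0.44 (adjusted p = 0.0714 without TRAMP_30wk replicate 2). The basal epithelial median was -1.06 (camera adjusted p = 0.000122, and adjusted p = 0.339 with an estimated correlation). Smooth muscle genes (3 of 18 lower, 8 adjusted over the list alone; median -0.80, adjusted p = 1.98e-05, and adjusted p = 0.339 with an estimated correlation) and endothelial markers (2 of 18, 2 adjusted over the list alone; median -1.15, adjusted p = 0.000122, and adjusted p = 0.499 with an estimated correlation) shifted down as well. The endothelial median was -1.81 without wild_type replicate 1 and -0.46 without wild_type replicate 2.

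Prostate secretory products had no gene past the test among 23, over all genes or adjusted over the list alone, although the list passed as a whole (median -0.96, adjusted p = 0.0192, and adjusted p = 0.499 with an estimated correlation). The untreated tumours parted here: the list's median level was 8.98 in replicate 1 and 13.61 in replicate 2, against 13.62 and 13.23 in wild type. The median difference was 0.08 without TRAMP_30wk replicate 1, -1.81 without TRAMP_30wk replicate 2 and -1.54 without wild_type replicate 2. This list also holds seminal vesicle secretory genes such as Svs4, so its median does not stand for prostate products alone. The probasin gene Pbsn went the other way, with an intensity of 1260.8 on TRAMP_30wk replicate 1 and 210.5, not above background, on replicate 2. Luminal and androgen response genes had 1 of 16 lower, 1 adjusted over the list alone, the prostatic acid phosphatase gene Acpp (-2.27 ± 0.22, above background on 1 of 2 tumour arrays; list adjusted p = 0.197). Endoplasmic reticulum secretory genes (median -0.24, adjusted p = 0.0245, and adjusted p = 0.499 with an estimated correlation), B and plasma cell markers (median -1.13, or -0.97 with members at their bound, adjusted p = 0.0243, and adjusted p = 0.499 with an estimated correlation) and neutrophil and myeloid suppressor genes (median -0.65, or -0.44 with members at their bound, adjusted p = 0.0243, and adjusted p = 0.499 with an estimated correlation) passed as lists with 1, 0 and 1 members lower over all genes and the same numbers adjusted over the list alone; each of these calls was lost with 1 array left out. The adjusted p for endoplasmic reticulum genes was 0.259 without wild_type replicate 1 and 0.151 without TRAMP_30wk replicate 2, and the median was -0.16 without wild_type replicate 1 and -0.43 without wild_type replicate 2. Without wild_type replicate 2 it was 0.33 for B and plasma cells and 0.435 for neutrophil genes, with medians of -0.22 and 0.24, and the neutrophil median was -0.43 without TRAMP_30wk replicate 2. Without TRAMP_cromolyn replicate 2 these were 0.0517 and 0.0707, and for B and plasma cells it was 0.0531 without TRAMP_30wk replicate 2. Lists that did not pass were epithelial junction (adjusted p = 0.054), mesenchymal transition (0.822), neuroendocrine and neural transcription factors (0.766), p53 targets (0.633), matrix metalloproteinases and inhibitors (0.28), fibroblast and collagen (0.766), hypoxia and glycolysis (0.979; median -0.02, mean -0.01) and erythrocyte genes (0.0536). Of these, epithelial junction genes passed upward without wild_type replicate 2, TRAMP_30wk replicate 1 or TRAMP_cromolyn replicate 3 (adjusted p = 0.0143, 0.036 and 0.0106). Erythrocyte genes passed downward without TRAMP_30wk replicate 1, TRAMP_cromolyn replicate 1 or TRAMP_cromolyn replicate 3 (0.0428, 0.0375 and 0.0291), and fibroblast genes downward without wild_type replicate 1 (0.0414).

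The counts between untreated TRAMP and wild type rested on all 4 arrays. Genes higher numbered 155 without TRAMP_30wk replicate 1, 106 without TRAMP_30wk replicate 2, 286 without wild_type replicate 1 and 230 without wild_type replicate 2, and genes lower 111, 96, 332 and 188 in the same order (610 without TRAMP_cromolyn replicate 2, which enters the pooled spread). Of the 58 genes that passed among those chosen to be named, 23 passed with each array left out in turn.

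The cromolyn tumours differed from untreated TRAMP in many more genes than untreated TRAMP did from wild type. As lists, neuroendocrine granule and cell cycle genes shifted up, and epithelial junction, smooth muscle, interferon response and antigen presentation genes shifted down. Of these, neuroendocrine granule genes also passed with an estimated correlation (adjusted p = 0.0414), and the others did not (adjusted p = 0.157 for cell cycle, 0.157 for epithelial junction, 0.166 for smooth muscle, 0.157 for interferon response and 0.35 for antigen presentation genes, each with an estimated correlation). Counts were 2463 genes higher and 2359 lower, 37.0% of those tested, of which 140 and 192 differed at least 16-fold. With cyclic loess higher and lower genes numbered 2188 and 2574, and with centring 2418 and 2400. Eef1a2, a translation elongation factor gene of neurons and muscle, rose at least 206-fold (adjusted p = 1.75e-05), Gprin1 at least 139-fold, Ddc, which encodes the decarboxylase that makes dopamine and serotonin, at least 105-fold, and Insm1, a neuroendocrine transcription factor gene, at least 95.8-fold. Rtn1 rose by 7.65 ± 0.19, Nnat by 7.05 ± 0.82 and Diras1 by 6.47 ± 0.17, the last 2 above background on 1 of 2 untreated arrays, and Syp by 6.40 ± 0.18. Tgm4, the prostate transglutaminase gene, fell at least 271-fold. Tcaf2 fell by 7.09 ± 0.36 on the log2 scale. Further large falls were in Defb50 (-8.14 ± 1.28), Msmb (-8.06 ± 0.67), Ctse (-8.05 ± 0.61), Myh11 (-7.04 ± 0.23) and Upk1b (-6.98 ± 0.66), each above background on 1 of 3 cromolyn arrays, and in Fxyd3 (-7.18 ± 1.13), above it on 2 of 3.

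Neuroendocrine granule and synaptic genes rose with cromolyn in 19 of 26 cases, 21 adjusted over the list alone. The neuroendocrine granule median was 4.22, or 3.93 with members at their bound (camera adjusted p = 8.09e-11, and adjusted p = 0.0414 with an estimated correlation). Scg3, a granule protein gene, rose at least 54-fold, Gap43 at least 69.7-fold, Chga, which encodes chromogranin A, at least 16.4-fold, and Uchl1 by 5.16 ± 0.24. Neuroendocrine and neural transcription factors and regulators rose in 10 and fell in 2 of 23, 11 and 2 adjusted over the list alone, with Elavl3 at least 32.8-fold, Prox1 at least 21.7-fold and Myt1 at least 22.2-fold higher. The transcription factor median was 1.67, or 1.26 with members at their bound (camera adjusted p = 0.000413, and adjusted p = 0.174 with an estimated correlation). Foxa2, above background on all cromolyn and no untreated TRAMP arrays, was at least 2.6-fold higher on average and did not pass (adjusted p = 0.187, and 0.0272 without TRAMP_cromolyn replicate 1). That fold came mainly from TRAMP_cromolyn replicate 1, with an intensity of 1842.3. The other cromolyn arrays read 252.8 and 218.9, near the limit of 216.9, so it does not describe them. It also rests on 1 of 2 probes. The other Foxa2 probe was not above background on any array and read 193.2 on TRAMP_cromolyn replicate 1. Cell cycle and E2F target genes rose in 30 of 34, 30 adjusted over the list alone, with Rrm2, a ribonucleotide reductase subunit gene, at 3.49 ± 0.23, Foxm1 at 1.83 ± 0.18 and Ezh2 at 1.53 ± 0.15. The cell cycle median was 1.39 (camera adjusted p = 4.46e-11, and adjusted p = 0.157 with an estimated correlation). Beside these groups, Schwann cell and nerve genes went both ways, 3 higher and 2 lower of 9 over all genes and adjusted over the list alone (list adjusted p = 0.539), with Prph at 4.53 ± 0.47.

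All 14 epithelial junction genes fell, over all genes and adjusted over the list alone, including Cdh1, the E-cadherin gene (-4.83 ± 0.51, above background on 1 of 3 cromolyn arrays), and St14 (-4.99 ± 0.20, on 1 of 3). The epithelial junction median was -3.98 (camera adjusted p = 1.15e-09, and adjusted p = 0.157 with an estimated correlation). Luminal and androgen response genes fell in 11 and rose in 1 of 16, over all genes and adjusted over the list alone, with the luminal keratin genes Krt8 at -6.96 ± 0.81 (on 2 of 3) and Krt18 at -6.20 ± 0.58 (on 1 of 3). The luminal median was -4.40 (camera adjusted p = 1.15e-05, and adjusted p = 0.157 with an estimated correlation). Prostate secretory products fell in 10 of 23, 10 adjusted over the list alone, and Wfdc15b fell at least 52.1-fold. The secretory product median was -4.44 (camera adjusted p = 8.37e-07, and adjusted p = 0.197 with an estimated correlation). Secretory levels differed between the untreated arrays (8.98 and 13.61). The median was -6.96 without TRAMP_30wk replicate 1 and -1.37 without TRAMP_30wk replicate 2, with cromolyn levels of 6.62 to 6.80, below the background limit. Pbsn, which encodes probasin, was above background on 1 of 2 untreated TRAMP arrays and on no cromolyn array (adjusted p = 0.124; 0.00785 without TRAMP_30wk replicate 2). Basal epithelial markers fell in 6 of 14, 8 adjusted over the list alone, with Trp63 at least 6.98-fold and Krt5 at least 3.04-fold lower. The basal epithelial median was -1.86, or -1.45 with members at their bound (camera adjusted p = 0.0293, and adjusted p = 0.513 with an estimated correlation). The list's call was lost without TRAMP_cromolyn replicate 1 (adjusted p = 0.0546), and that of Krt5 without TRAMP_30wk replicate 1 (0.0738) or replicate 2 (0.0752). Endoplasmic reticulum secretory genes fell in 13 and rose in 1 of 24, 15 and 1 adjusted over the list alone, among them Pdia4 (-2.01 ± 0.19). The endoplasmic reticulum median was -0.995 (camera adjusted p = 2.35e-05, and adjusted p = 0.35 with an estimated correlation).

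Smooth muscle genes fell beside the epithelial genes, 16 of 18 over all genes and 16 adjusted over the list alone, with Mylk at -5.54 ± 0.29, Tpm2 at -5.77 ± 0.31 and Tagln at -5.02 ± 0.26 (above background on 2 of 3 cromolyn arrays). The smooth muscle median was -3.54, or -3.39 with members at their bound (camera adjusted p = 2.43e-10, and adjusted p = 0.166 with an estimated correlation). Fibroblast and collagen genes fell in 8 of 22, 8 adjusted over the list alone, among them Ogn (-4.44 ± 0.61, on 2 of 3). The fibroblast median was -1.66 (camera adjusted p = 0.000275, and adjusted p = 0.513 with an estimated correlation). Endothelial markers had 1 of 18 higher over all genes, Plvap (2.30 ± 0.73), and 0 adjusted over the list alone (list median 0.21, adjusted p = 0.521). Plvap lost its call with any untreated TRAMP or cromolyn array left out, at adjusted p from 0.0576 without TRAMP_cromolyn replicate 3 to 0.183 without TRAMP_30wk replicate 2. Interferon response genes fell in 20 of 27, 23 adjusted over the list alone, with Isg15 at -3.70 ± 0.32 and Oasl2 at -3.49 ± 0.28. The interferon response median was -1.92 (camera adjusted p = 2.43e-10, and adjusted p = 0.157 with an estimated correlation). Antigen presentation genes fell in 11 of 20, 11 adjusted over the list alone, with H2-T23 at -4.21 ± 0.27 and Tapbp at -3.06 ± 0.22. The antigen presentation median was -2.29 (camera adjusted p = 8.13e-07, and adjusted p = 0.35 with an estimated correlation). Immune cell markers fell in smaller numbers beside them: T and NK cells 3 of 17, 2 adjusted over the list alone (median -0.52, adjusted p = 0.0131, and adjusted p = 0.542 with an estimated correlation), and macrophages 1 of 17, Cd14 (-2.97 ± 0.56), also adjusted over the list alone (median -0.85, or -0.68 with members at their bound, adjusted p = 0.0351, and adjusted p = 0.789 with an estimated correlation). Without TRAMP_30wk replicate 2 the adjusted p of Cd14 was 0.0543. Matrix metalloproteinases and inhibitors fell in 7 and rose in 2 of 21, 8 and 2 adjusted over the list alone: Mmp9 fell by 1.49 ± 0.17 and Mmp7 at least 12.3-fold. The metalloproteinase median was -0.94 (camera adjusted p = 0.0385, and adjusted p = 0.35 with an estimated correlation). Immediate early and heat shock genes fell in 8 and rose in 2 of 19, 9 and 2 adjusted over the list alone, with Hspb1 at -4.22 ± 0.31. The immediate early median was -0.88 (camera adjusted p = 0.0236, and adjusted p = 0.542 with an estimated correlation).

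Lists that did not pass between cromolyn and untreated TRAMP were mesenchymal transition (adjusted p = 0.57; Vim 0.61 ± 0.68), p53 targets (0.261), B and plasma cells (0.521), neutrophil and myeloid suppressor (0.471), hypoxia and glycolysis (0.57), skeletal muscle (0.681; median 0.10, mean -0.34), adipocyte (0.29) and erythrocyte genes (0.782; median 0.25, test upward, mean -0.0014). The macrophage list lost its call without TRAMP_30wk replicate 1 (adjusted p = 0.0667), TRAMP_cromolyn replicate 1 (0.139, with a median of -0.55) or TRAMP_cromolyn replicate 2 (0.0588). The matrix metalloproteinase list lost its call without TRAMP_30wk replicate 2 (0.105), TRAMP_cromolyn replicate 1 (0.0562) or TRAMP_cromolyn replicate 2 (0.0607), and the immediate early list without TRAMP_cromolyn replicate 1 (0.0554, with a median of -0.52). Genes higher and lower numbered 1115 and 1313 without TRAMP_30wk replicate 1, and 1149 and 1336 without TRAMP_30wk replicate 2. Of the 99 genes that passed among those chosen to be named, 85 passed with each array left out in turn.

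**Figure D2:**
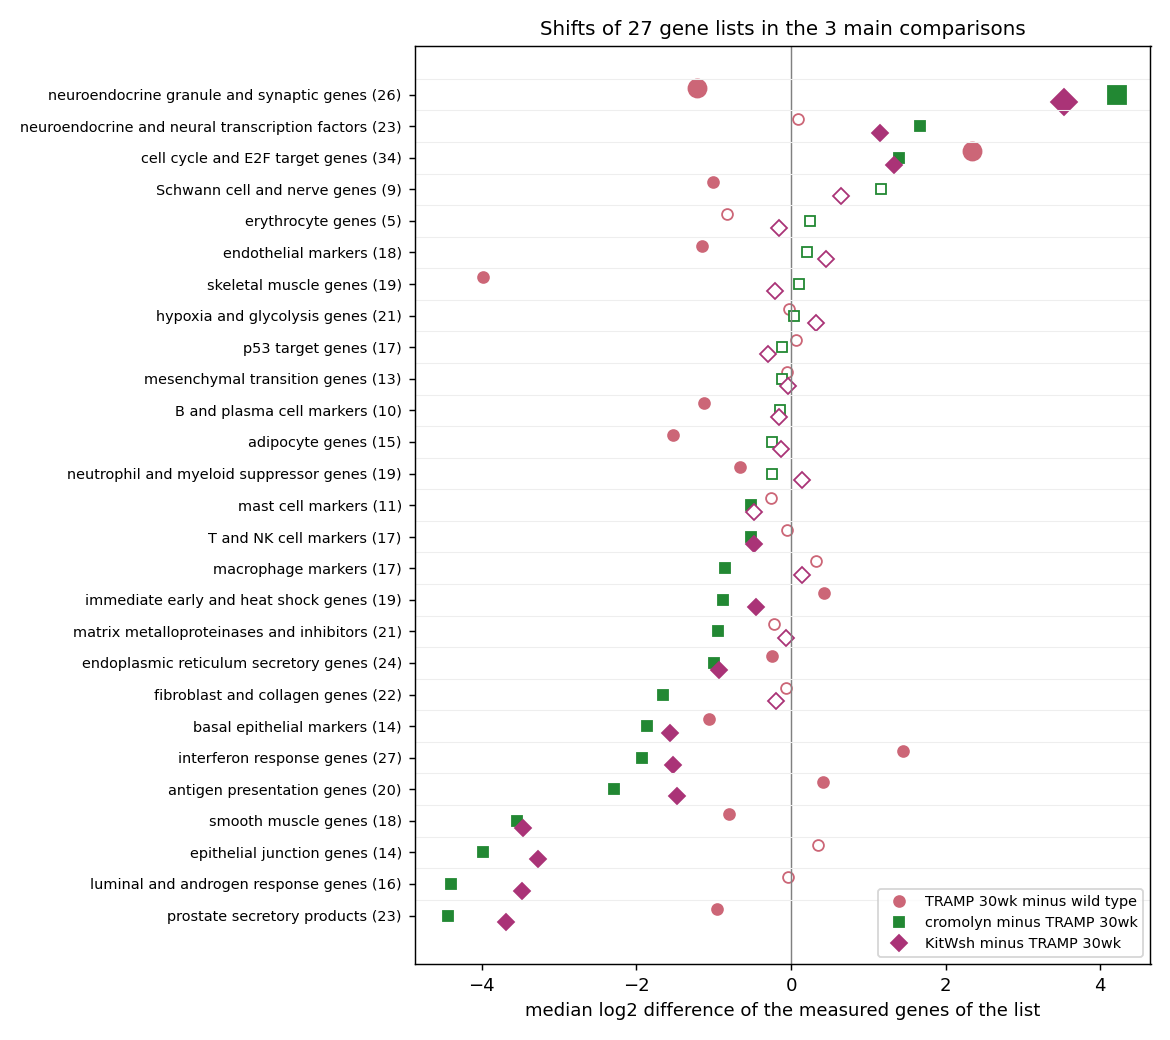
Points give the median log2 difference over the measured genes of each of 27 lists (number measured in brackets) in 3 comparisons; filled points passed camera at adjusted p under 0.05 with the preset correlation, and larger filled points also with an estimated correlation. Neuroendocrine granule and synaptic genes lay at 4.22 with cromolyn (3.93 with members at their bound) and 3.54 with KitW-sh, and epithelial junction genes at -3.98 and -3.27.

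The KitW-sh tumour, set against the same untreated TRAMP arrays, had neuroendocrine granule and cell cycle genes shifted up and epithelial junction, smooth muscle and interferon response genes shifted down as lists. Of these, neuroendocrine granule genes also passed with an estimated correlation (adjusted p = 0.0479), and the others did not (adjusted p = 0.183 for cell cycle, 0.183 for epithelial junction, 0.183 for smooth muscle and 0.209 for interferon response genes, each with an estimated correlation). With 1 array it was taken to vary like the other groups. Counts were 1487 genes higher and 1463 lower, of which 134 and 109 differed at least 16-fold. They numbered 1358 and 1570 with cyclic loess and 1469 and 1486 with centring. The largest rises were in Ddc (at least 259-fold, adjusted p = 0.00399), Eef1a2 (at least 193-fold), Insm1 (at least 180-fold), Diras2 (at least 165-fold) and Gprin1 (at least 155-fold), followed by Rtn1 (7.85 ± 0.26), Nnat (7.74 ± 1.10) and Diras1 (6.57 ± 0.23), the last 2 above background on 1 of 2 untreated arrays. The largest falls were in Tgm4 (at least 271-fold), Ctse (at least 208-fold), Myh11 (at least 128-fold) and Pate14 (at least 91.5-fold), and in Rnase1 (-7.34 ± 1.76), Tcaf2 (-6.89 ± 0.48), Psca (-6.02 ± 0.91) and the skeletal actin gene Acta1 (-5.99 ± 1.02). Diras2 and Rnase1 lost their calls without TRAMP_30wk replicate 1 (adjusted p = 0.0514 and 0.114) or replicate 2 (0.0539 and 0.0877), and Rnase1 also without either wild-type array (0.0528 each).

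Neuroendocrine granule and synaptic genes rose with KitW-sh in 17 of 26, 17 adjusted over the list alone, with Syp at 5.75 ± 0.25 and Chga at least 56.9-fold higher. The neuroendocrine granule median was 3.54 (camera adjusted p = 3.27e-10, and adjusted p = 0.0479 with an estimated correlation). Transcription factors of these cells rose in 8 and fell in 2 of 23, 8 and 3 adjusted over the list alone, with Nkx2-2 at least 20.7-fold higher. The transcription factor median was 1.15, or 0.73 with members at their bound (camera adjusted p = 0.00527, and adjusted p = 0.275 with an estimated correlation). Cell cycle genes rose in 26 of 34, 30 adjusted over the list alone, including Rrm2 (3.96 ± 0.31). The cell cycle median was 1.33 (camera adjusted p = 1.39e-11, and adjusted p = 0.183 with an estimated correlation). Epithelial junction genes fell in 12 of 14, 14 adjusted over the list alone, with Cdh1 at -3.03 ± 0.68 and St14 at -4.33 ± 0.26. The epithelial junction median was -3.27 (camera adjusted p = 1.88e-08, and adjusted p = 0.183 with an estimated correlation). Luminal and androgen response genes fell in 11 of 16, over all genes and adjusted over the list alone (median -3.48, adjusted p = 6.11e-05, and adjusted p = 0.183 with an estimated correlation), with Krt8 at -4.41 ± 1.09, and secretory products in 5 of 23, 5 adjusted over the list alone (median -3.69, or -3.40 with members at their bound, adjusted p = 2.2e-05, and adjusted p = 0.275 with an estimated correlation). The secretory median was -5.69 without TRAMP_30wk replicate 1 and -2.13 without TRAMP_30wk replicate 2. Basal epithelial markers fell in 3 of 14, 5 adjusted over the list alone, with Trp63 at least 6.98-fold lower. The basal epithelial median was -1.56, or -1.32 with members at their bound (camera adjusted p = 0.013, and adjusted p = 0.504 with an estimated correlation). Smooth muscle genes fell beside them in 15 of 18, 16 adjusted over the list alone, with Mylk at -4.97 ± 0.39. The smooth muscle median was -3.47, or -3.08 with members at their bound (camera adjusted p = 3.73e-11, and adjusted p = 0.183 with an estimated correlation). Interferon response genes fell in 14 of 27, 15 adjusted over the list alone (median -1.53, adjusted p = 7.82e-08, and adjusted p = 0.209 with an estimated correlation), with Rsad2 at -2.53 ± 0.31, and antigen presentation genes in 9 of 20, 11 adjusted over the list alone (median -1.48, adjusted p = 0.000139, and adjusted p = 0.532 with an estimated correlation), with H2-T23 at -3.15 ± 0.36. Endoplasmic reticulum secretory genes fell in 6 of 24, 9 adjusted over the list alone. The endoplasmic reticulum median was -0.93 (camera adjusted p = 0.000208, and adjusted p = 0.476 with an estimated correlation). T and NK cell markers (1 of 17 lower, 0 adjusted over the list alone; median -0.47, or -0.36 with members at their bound, adjusted p = 0.0391, and adjusted p = 0.79 with an estimated correlation) and immediate early genes (5 lower and 1 higher of 19, 7 and 2 adjusted over the list alone; median -0.45, adjusted p = 0.0391, and adjusted p = 0.693 with an estimated correlation) passed as lists, and both calls were lost with 1 array left out. The adjusted p for T and NK cells was 0.105 without TRAMP_30wk replicate 2 and 0.0551 without TRAMP_cromolyn replicate 2, and for immediate early genes 0.0507 without TRAMP_cromolyn replicate 2. Without TRAMP_30wk replicate 1 or replicate 2 the calls of Cdh1 (0.0882 and 0.0915) and Krt8 (0.106 and 0.114) were lost, and that of Krt8 also without either wild-type array (0.0545 each).

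Stromal and immune lists that passed with cromolyn did not all pass with KitW-sh: fibroblast and collagen genes had a median of -0.19 (adjusted p = 0.282), macrophage markers 0.14 (0.868) and matrix metalloproteinases -0.06 (0.50). Tested directly between KitW-sh and cromolyn, these lists had adjusted p of 8.36e-07, 1.13e-05 and 0.014, and adjusted p = 0.471, 0.664 and 0.471 with an estimated correlation. Mesenchymal transition (median -0.04, mean 0.16), p53 target, endothelial, B and plasma cell, neutrophil (median 0.15, mean -0.04), hypoxia, skeletal muscle, adipocyte, Schwann cell and erythrocyte lists did not pass either, with adjusted p from 0.202 to 0.971. Genes higher and lower numbered 569 and 646 without TRAMP_30wk replicate 1, 567 and 639 without TRAMP_30wk replicate 2, and 3165 and 3036 with only these 2 groups in the fit. Not all of the 83 genes that passed among those chosen to be named kept their calls with 1 other array left out. The lone KitW-sh array could not be left out, so its side of the comparison was not tested this way.

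Both 24-week groups were compared through the same untreated TRAMP arrays. Across genes, the log2 differences correlated at 0.928, and in 100 simulations of unchanged groups against those shared arrays the correlation averaged 0.449 and reached 0.502. The covariance was 1.68 against 0.0713 in the simulations, a difference of 1.60. There were 1364 genes higher in both (281.2 if the lists were independent) and 1406 lower in both (265.0 if independent), and 4 in opposite directions, so 93.9% of the KitW-sh calls were also called with cromolyn in the same direction. The 2 lists share the untreated arrays and so are not independent. In the simulations of unchanged groups at most 0 genes were called in both in the same direction. Where nothing changes hardly any gene is called in either comparison, so this count gives no expected overlap for these data. The simulated noise was independent between genes, so the range of simulated correlations may be too narrow. With the untreated arrays split so that no control was shared, the correlation was 0.885 with TRAMP_30wk replicate 1 for cromolyn and replicate 2 for KitW-sh, and 0.889 the other way round, with covariances of 1.63 and 1.64.

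**Figure D3:**
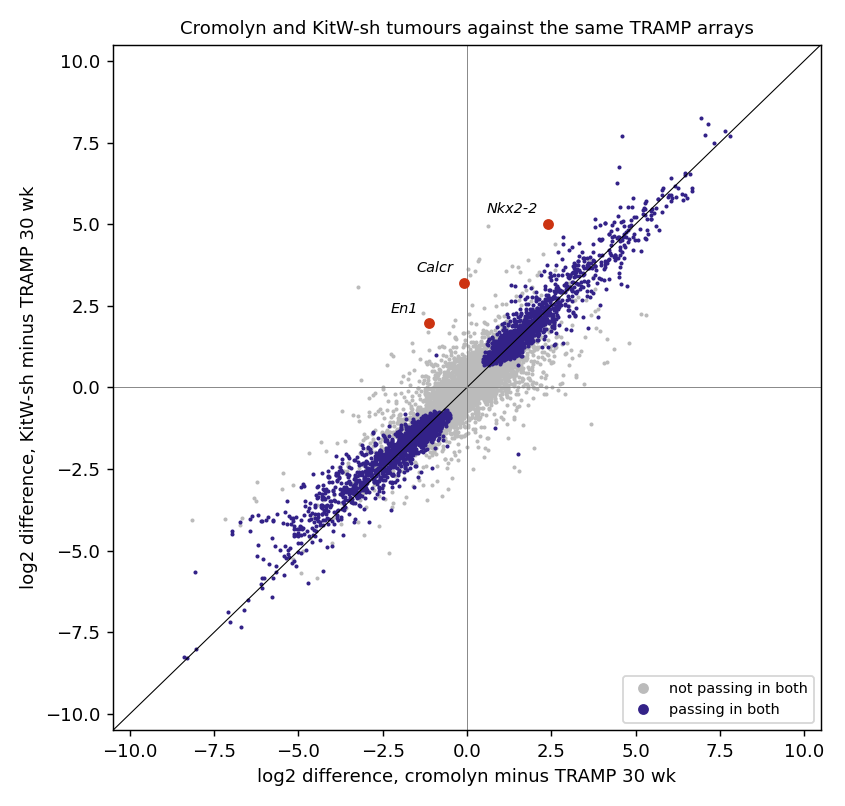
Each point is a gene, with its log2 difference from untreated TRAMP for cromolyn on the horizontal and for KitW-sh on the vertical axis; dark points passed the test in both, and the line marks equal differences. Nkx2-2, Calcr and En1 are the 3 genes whose difference between KitW-sh and cromolyn passed.

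Against wild-type prostate the 24-week tumours differed in more genes than the untreated tumours did. Cell cycle genes rose in all 34 measured cases with cromolyn, also adjusted over the list alone (median 3.89, adjusted p = 2.32e-20, and adjusted p = 0.0703 with an estimated correlation), and in 33 with KitW-sh, 34 adjusted over the list alone (median 3.88, adjusted p = 9.0e-24, and adjusted p = 0.0907 with an estimated correlation). Genes numbered 2999 higher and 2980 lower with cromolyn and 2069 higher and 1992 lower with KitW-sh. This near-even split depended on the scaling: with cyclic loess higher and lower genes numbered 2566 and 3325 with cromolyn and 1818 and 2249 with KitW-sh, and with centring 2722 and 3194 and 1891 and 2147. Insm1 rose at least 95.9-fold with cromolyn and at least 180-fold with KitW-sh, Nnat by 6.44 ± 0.82 and 7.13 ± 1.10, and Ly6h, above background on 1 of 2 wild-type arrays, by 6.91 ± 0.21 and 7.03 ± 0.28. Tgm4 fell at least 506-fold with cromolyn and at least 506-fold with KitW-sh. The seminal vesicle secretory gene Svs4 fell by 8.38 ± 1.98 with cromolyn, where it was above background on 1 of 3 arrays, and at least 476-fold with KitW-sh, with adjusted p of 0.0136 and 0.0409 that became 0.0716 and 0.115 without wild_type replicate 2 and 0.0645 and 0.108 without wild_type replicate 1. With KitW-sh it was also 0.0594 without TRAMP_cromolyn replicate 1 and 0.0601 without TRAMP_cromolyn replicate 3. Interferon response genes had medians of -0.24 (adjusted p = 0.0622) and 0.10 (adjusted p = 0.66). Skeletal muscle genes fell in all 19 and 19 measured cases, also adjusted over the list alone, with medians of -4.03, or -3.73 with members at their bound and -4.56, or -4.37 with members at their bound (adjusted p = 2.7e-10 and 5.71e-12, and adjusted p = 0.182 and 0.211 with an estimated correlation). Mast cell markers fell in 6 of 11 with cromolyn, 6 adjusted over the list alone (median -0.72, or -0.55 with members at their bound, adjusted p = 0.0081, and adjusted p = 0.331 with an estimated correlation), and in 2 with KitW-sh, 2 adjusted over the list alone (adjusted p = 0.0646); Cpa3 fell at least 4.08-fold and at least 4.09-fold. Genes higher with cromolyn numbered 1975 without wild_type replicate 2.

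Few genes passed between KitW-sh and cromolyn tumours. Only 3 genes passed in limma, all higher with KitW-sh: the homeobox gene En1 (at least 6.71-fold, adjusted p = 0.0369), the calcitonin receptor gene Calcr (at least 6.5-fold, adjusted p = 0.0433) and the homeobox gene Nkx2-2 (2.59 ± 0.22, adjusted p = 0.0433), with 709 genes at an unadjusted p under 0.05. None of the 3 passed without either wild-type array, either untreated TRAMP array or TRAMP_cromolyn replicate 1, at adjusted p from 0.0808 without TRAMP_cromolyn replicate 1 to 0.281 without TRAMP_30wk replicate 1. Genes higher and lower numbered 24 and 7 without TRAMP_cromolyn replicate 3 and 9 and 10 without TRAMP_cromolyn replicate 2. With the preset correlation 8 of 27 lists passed upward with KitW-sh and 2 downward, and 0 passed with an estimated one. Upward they were fibroblast and collagen (median 1.04, adjusted p = 8.36e-07), interferon response (0.42, 1.96e-06), epithelial junction (0.66, 5.57e-06), macrophage (1.04, 1.13e-05), antigen presentation (0.50, 0.000348), luminal and androgen response (0.41), metalloproteinase (0.41) and neutrophil genes (0.26; adjusted p = 0.014 for each of the last 3). Downward they were neuroendocrine granule (-0.39) and skeletal muscle genes (-0.38, or -0.23 with members at their bound; adjusted p = 0.014 each). With an estimated correlation the adjusted p of these 10 lists was 0.471 or 0.664. Interferon response, epithelial junction, antigen presentation, luminal and neuroendocrine granule genes thus had medians nearer to untreated TRAMP with KitW-sh than with cromolyn. Median levels on the lone KitW-sh array and the cromolyn range were 11.25 and 11.29 to 11.65 for neuroendocrine granule genes. For luminal genes they were 7.49 and 6.94 to 7.36, and for epithelial junction genes 8.35 and 6.81 to 7.57. Neuroendocrine granule and luminal levels thus lay just outside that range. The brightest Chga probe went the other way, at 7433 with KitW-sh and 1221 to 3521 with cromolyn. No member of the fibroblast or macrophage list passed, over all genes or adjusted over the list alone. Krt8 differed by 2.55 ± 1.02 (adjusted p = 0.894) and Cdh1 by 1.80 ± 0.64 (adjusted p = 0.844), on 2 of 3 and 1 of 3 cromolyn arrays above background, and both had an adjusted p of 0.0414 without TRAMP_cromolyn replicate 3.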

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

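The following tests were planned as the difference between the 24-week groups, and the genes were named after their values were seen. En1, Calcr and Nkx2-2 were singled out because the effects of KitW-sh and cromolyn against untreated TRAMP differed by a test of the difference itself. En1 was at least 6.71-fold higher with KitW-sh (fitted log2 difference 3.09, adjusted p = 0.0369), at 9.76 against 6.79, 6.61 and 6.59 on the cromolyn arrays, none above background, so that its fitted difference is not a measured size. The same holds for Calcr, at least 6.5-fold higher (fitted log2 difference 3.31, adjusted p = 0.0433), at 9.71 against 6.66, 6.23 and 6.33. Nkx2-2, above background in both groups, was 2.59 higher on the log2 scale (adjusted p = 0.0433), at 11.39 against 8.61, 8.85 and 8.93. With only these 2 groups in the fit the adjusted p values were 0.896, 0.896 and 0.896. The calls were also lost without either wild-type array (0.121 for each of the 3), without TRAMP_cromolyn replicate 1 (0.0808 for each), and without either untreated TRAMP array (0.208 for En1 and Calcr, 0.281 for Nkx2-2). A single KitW-sh array stands behind these values, and no explanation was tested.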

How the results depend on the processing

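The normexp offset of 16, the centring on genes above background on all arrays, the split of the untreated arrays and the separate parts of the estimated-correlation test were chosen only after the result was seen. Over all alternatives, named genes kept their side of the threshold in 6503 cases, lost the call in 298 and gained it in 109, and lists did so in 1354, 77 and 23. Direction was compared only where a gene or list passed in the main fit or the alternative. Among these, the test direction of 4 lists turned between untreated TRAMP and wild type. They were secretory products (median 0.083 without TRAMP_30wk replicate 1), macrophages (-0.75) and T and NK cells (-0.25, both without wild_type replicate 1), and neutrophil genes (0.24 without wild_type replicate 2). For T and NK cells the median was already -0.05 with all arrays, so its sign did not turn there. With 1 array left out these medians ranged from -1.81 to 0.083, -0.75 to 1.11, -0.25 to 0.28 and -0.98 to 0.24. Of 45 list calls in the main comparisons 4 held with an estimated correlation, a test that also has 4 degrees of freedom in place of 13023. The estimated correlations alone left 19 calls and the 4 degrees of freedom alone 28. For neuroendocrine granule genes the estimate was -0.0154, below the preset value, so their larger adjusted p values came with the degrees of freedom. With 1 array left out there were 38 to 47 calls. With only the 2 groups compared, untreated TRAMP against wild type had 799 genes higher and 669 lower, KitW-sh against untreated TRAMP 3165 and 3036, and KitW-sh against cromolyn 0 and 0. A log2 difference of at least 1 left 1593 genes higher with cromolyn than in untreated TRAMP, by its own construction. KitW-sh against cromolyn gave 5 genes higher and 1 lower with cyclic loess, 5 and 2 with no filter, 3 and 1 with an intensity trend, 1 and 0 with a filter on 2 arrays, and 1 and 0 with an offset of 16. With 1 array left out, genes higher and lower numbered 106 to 701 and 96 to 610 for untreated TRAMP against wild type, 1115 to 2773 and 1313 to 2584 for cromolyn and 567 to 1966 and 639 to 1890 for KitW-sh against untreated TRAMP, 1975 to 3288 and 2257 to 3148 for cromolyn and 1417 to 2538 and 1451 to 2431 for KitW-sh against wild type, and 0 to 24 and 0 to 10 for KitW-sh against cromolyn, and the correlation of the shared direction was 0.901 to 0.930. Leaving out 1 of 2 arrays leaves a lone array in a group, assumed to vary like the others; the cause was not tested for any other change. The KitW-sh array could not be left out, and a slide block was not run. Signals near background limit what can be seen, since values below the limit give only bounds and genes below it on all arrays were not tested.

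With the replicate number as a block, untreated TRAMP against wild type had 244 genes higher and 174 lower, KitW-sh against untreated TRAMP 891 and 974, and KitW-sh against cromolyn 0 and 0. Deviations of same-numbered arrays of different groups correlated at 0.00198 to 0.0745 across genes, all positive but small. With so few arrays per group, these values cannot decide whether the numbers pair the samples. The cause of the changed counts with this block was not tested.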

Other observations

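The gene families here, and all tests below except that of muscle between the wild-type arrays and that of normalization for the interferon genes, were chosen only after the result was seen. Called genes were counted in 10 families against all other named genes with Fisher's exact test (two-sided, adjusted over 60 tests). With cromolyn, 10 of 21 keratin genes, which encode epithelial filaments, were lower than in untreated TRAMP (adjusted p = 0.0167), among them Krt7 (-3.63 ± 0.66) and Krt19 (-6.74 ± 1.09, above background on 1 of 3 cromolyn arrays). With KitW-sh 7 were lower (adjusted p = 0.0448) and 1, Krt20, was at least 13.8-fold higher. Protocadherin genes, which encode adhesion proteins of neurons, were higher with cromolyn in 14 of 32 cases (adjusted p = 0.0138), with Pcdha6 at least 11.3-fold and Pcdhb3 at least 7.01-fold higher, and in 7 with KitW-sh (adjusted p = 0.277). Synaptotagmin genes, which encode calcium sensors of vesicle release, were higher in 6 of 12 with cromolyn (adjusted p = 0.075) and in 6 with KitW-sh (adjusted p = 0.0138), led by Syt16 (4.76 ± 0.55 and 5.52 ± 0.74) and Syt11 (4.65 ± 0.26 and 4.37 ± 0.34). These family medians kept their signs with no background correction, median scaling, cyclic loess and centring. Several keratin genes also stand in lists given above, such as Krt7 and Krt19 (epithelial junction), Krt8 (luminal) and Krt5 (basal). The neuroendocrine granule list likewise holds Syt1, Syt4 and Syt7. The keratin and synaptotagmin counts are therefore not independent of the shifts of those lists.

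Between untreated TRAMP and wild type, 9 of 31 Hox genes, which set position along the body axis, were lower (adjusted p = 1.01e-05), among them Hoxb4 (-2.27 ± 0.23), Hoxb5 (-2.20 ± 0.19) and Hoxd4 (-2.50 ± 0.44). Defensin genes, many of them expressed in the epididymis, were lower in 7 of 19 (adjusted p = 1.99e-05), with Defb28 at least 6.46-fold and Defb11 at least 4.47-fold lower. Both medians kept their signs under the same 4 scalings. Of 55 cytosolic ribosomal protein genes, 1 was higher with cromolyn (Rps15a, 1.95 ± 0.22), a smaller share than among other genes (adjusted p = 0.00408), and 5 were lower (adjusted p = 0.27). With KitW-sh 0 were higher and 0 lower, in each direction a smaller share than among other genes (adjusted p = 0.0167 and 0.0167). Between untreated TRAMP and wild type their median was 0.05 and turned to -0.02 with cyclic loess and with centring.

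As lists, neuroendocrine granule genes shifted up and epithelial junction and smooth muscle genes down in the 24-week tumours against untreated TRAMP. With an estimated correlation only the neuroendocrine granule shift passed (adjusted p = 0.0414 with cromolyn and 0.0479 with KitW-sh), and not those of epithelial junction (0.157 and 0.183) and smooth muscle genes (0.166 and 0.183). Quantile normalization leaves ranks within an array as they were. The median rank of neuroendocrine granule genes on the lowest 24-week array lay 50.4 percentile points above that on the highest untreated array. Because all arrays share nearly the same distribution, this gap restates the difference in level. It shows that the ranks differed before that normalization too. It cannot exclude an effect of the normalization on the size of the differences. Displacement of all other cell types alike by neuroendocrine cells would lower smooth muscle and endothelial genes by a similar amount. Their medians differed by -3.75 with cromolyn (two-sided permutation p = 2e-05) and by -3.92 with KitW-sh. That permutation exchanged genes between the lists, and its p does not measure the spread between samples. The median level of smooth muscle genes was 7.30 to 7.52 on the 24-week arrays and 12.50 to 12.91 in untreated TRAMP. For endothelial genes it was 9.46 to 9.72 and 9.07 to 9.15, so smooth muscle and endothelial genes did not fall alike. This argues only against displacement of all other cell types alike, and the medians were known when the test was chosen. A change in cell composition that spares endothelial cells was not tested. A change in tumour type with age could give the pattern as well as the loss of mast cell function, and the series has 0 untreated TRAMP arrays at 24 weeks, so age, cromolyn and genotype cannot be told apart.

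Skeletal muscle genes shifted down as a list in untreated TRAMP against wild type, a call lost with an estimated correlation (adjusted p = 0.114). Muscle carried along in the wild-type samples may account for this. If its share differed between the wild-type arrays, the genes would then move as 1 block between them. An equal share in both would leave no such block, so the test cannot exclude it. Between those arrays 15 of 19 genes were higher on replicate 2, against the 16 set beforehand, while 19 of 19 were lower in untreated TRAMP, so this stays open, as does a change in the tissue itself. Adipocyte genes went the same way between the wild-type arrays, 13 of 15 higher on replicate 2. This direction was not particular to muscle and fat. Median levels on wild_type replicates 1 and 2 were 9.77 and 11.62 for endothelial and 8.51 and 10.51 for macrophage markers. Secretory products went the other way (13.62 and 13.23). The muscle genes had a median difference of -0.33 for replicate 1 minus replicate 2, against -3.99 for untreated TRAMP minus wild type. Tnnt3 was at 11.64 in wild type, and no gene of this list stands in another list.

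Interferon response genes shifted up as a list in untreated TRAMP against wild type, a call lost with an estimated correlation (adjusted p = 0.114). Their median rank on the lower tumour array lay 14.6 percentile points above that on the higher wild-type array. This gap, too, restates the difference in level. It shows that the ranks differed before the authors' normalization, but cannot exclude an effect of it on the size of the difference. Lymphoid markers had a median of -0.11 and lay below the interferon genes by 1.56 (permutation p = 1e-05, the smallest that 100000 permutations can give). The difference was 1.86 without wild_type replicate 1 and 1.40 without wild_type replicate 2. In untreated TRAMP the median level was 7.33 and 7.56 for T and NK cell markers and 7.06 and 7.12 for B and plasma cell markers. These levels lay near the limit of 7.01, where a rise may go unseen. The difference therefore cannot decide whether more lymphoid cells were a source. More macrophages may still contribute: the difference from their markers was 1.12 (permutation p = 0.0029), but it was 0.45 without wild_type replicate 2 (permutation p = 0.076) and 2.16 without wild_type replicate 1 (permutation p = 4e-05). Ctss is the 1 macrophage marker that also stands in another list, that of antigen presentation, and a response of the tumour itself was not tested.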
